A study of Danio rerio with 18 samples.

How the data were processed

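The series measured RNA of adult zebrafish spinal cord after cord transection (injury) or after a sham operation, an incision that left the cord intact. Per the labels, each of 18 arrays carries total RNA pooled from 5 animals aged 6 months, taken as a segment of 5 mm caudal to the lesion. The RNA was amplified with the NuGEN WT-Ovation kit, labelled with Cy3 and hybridized to 1-colour Agilent zebrafish arrays of design 015064. Injury and sham were sampled 4, 12 and 264 h after surgery, with 3 pools for each of the 6 groups, or 90 animals in all.

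The deposited scanner files give intensity per spot in linear units, and per the file headers they come from Feature Extraction 9.5.3.1 with protocol GE1-v5_95_Feb07. Per the file headers, the processed intensity was background-subtracted and spatially detrended within each array, and it was not scaled between arrays. The deposited files also hold other values per spot, 0 or 1 marks for signal well above background, saturation and outlier spots. A deposited value table gives 1 intensity per probe and array. Its processing is not stated in the sources used here; its values lay on the linear scale without centring, and 94.6% to 97.1% of probes per array were within 1% of the scanner signal averaged over a probe's spots. The step behind the remaining probes stays unknown, and a single-channel intensity has no direction. The column medians of that table for injury replicates 1 to 3 were 95.2, 114 and 118 at 4 h, 114, 121 and 115 at 12 h, and 100.02, 111 and 101 at 264 h. For sham replicates 1 to 3 they were 117, 101 and 117 at 4 h, 124, 102 and 121 at 12 h, and 91.4, 98.7 and 115 at 264 h.

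Each array held 42990 spots for 21495 probes, 2 spots per probe, besides 1417 control spots that were left out. Outlier spots, 0 to 21 per array, were left out, and the log2 of the mean processed intensity of the remaining spots was taken. Each array's 75th percentile was then subtracted. A probe was tested when it was well above background on at least 3 of the 18 arrays, which kept 18504 probes and left out 2991. Where no array of a group was well above background for a probe, its fold change is a bound written as "at least". The bound sets that group at each array's lowest level marked above background, −7.65 to −6.11 on the log2 scale. That level is no detection limit: the gene gypc, at −5.921 to −5.555 on the injured 4 h arrays, was above background on 2 of 3. A higher limit would give a smaller bound. Probes were named from the reference tables by accession for 7347, by symbol for 588 and by synonym for 2337. The other 11218 kept the name in the files, and 5 matched several symbols. In all, 10058 probes carried a gene symbol, for 7014 distinct symbols. No genome was used, so no positions are given.

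All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 6 group means, 12 residual degrees of freedom and 2.3 prior degrees of freedom. The contrasts were injury minus sham at each of the 3 times and the differences of these effects between times. The tests were two-sided, with Benjamini-Hochberg adjustment over the 18504 probes and a threshold of 0.05 on the adjusted p. The number of arrays, 3 per group, limits the precision. The labels carry no numbers that pair injury with sham pools, so no pairing was used.

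Gene lists, 19 in number, were tested with camera at a preset correlation of 0.01 between genes. That test used 1 probe per gene, the one with the highest mean intensity, over 6509 genes, of which 1987 had several tested probes. Adjustment covered the 57 tests of 19 lists and 3 times. Camera with an estimated correlation, fry, and a mean over all probes of a gene were run beside it. A list's shift is the mean log2 change of its genes minus that of the other genes. Samples, contrasts, lists, named-gene rule and the alternatives, except removal of slide 1, were fixed before the data were examined.

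The rule for named genes takes, at each time, the 12 called genes with the largest rise and the 12 with the largest fall whose 3 injured arrays all lie on 1 side of the 3 sham arrays. It adds up to 4 called members of each list and, always, the follow-up genes of the research field with gap43, gfap, mbpa and atf3. Where fewer than 5 genes pass, it takes the 5 with the smallest unadjusted p in each direction. Names that are only clone or database identifiers count as unnamed. The text pattern that applies this was corrected after values had been seen, because it had also excluded true symbols such as those of solute carriers, from the list tests as well. For differences between times it takes the 5 named genes with the smallest adjusted p in each direction. In the tests, a group of 3 arrays lies wholly above or below another 3 by chance in 10% of cases.

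Alternatives for scaling were quantile normalization and a 75th percentile over the 14124 probes above background on all arrays. The alternative for background was normexp correction with an offset of 50. Alternatives for the filter were none, with 21495 probes, or 9 arrays, with 17072. Alternatives for the model were the arrays of the compared times alone, slide as a fixed or a random block, a trended and robust prior, array weights, each array left out in turn, and the value table in place of the scanner signals. In the random block the correlation within slides was 0.073. The arrays lay on 5 slides. Slide 1 held injury and sham replicate 1 of 264 h, and slide 2 held replicates 2 and 3 of both. Slide 3 held injury 12 h replicate 1 and the 3 sham 12 h arrays. Slide 4 held sham 4 h replicates 1 and 2 with injury 12 h replicates 2 and 3. Slide 5 held the 3 injury 4 h arrays and sham 4 h replicate 3. Replicate numbers here follow the order of the labels.

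The labels of sham 264 h replicate 1 conflict: its title says injury and its treatment says sham. It was taken as sham because the design text gives 3 pools per group, and it was also left out or counted as injured as alternatives. For gap43, sox11b and atf3, named whatever their values and called at 264 h also without this array, its log2 levels were 5.80, 1.48 and 0.28. The other sham arrays had 5.76 and 5.78, 1.46 and 1.42, and 0.265 and 1.22. The lowest injured levels were 7.08, 2.615 and 1.84. For gap43 and atf3 the levels argue against counting the array as injured. sox11b is on the list drawn from later work of the field, so it is not independent evidence here. The pipeline was tested on simulated data with 200 of 18504 probes changed. At 4, 12 and 264 h it recovered 56.7%, 50.7% and 50.7% of 2-fold changes, and 77.3%, 78.8% and 75.8% of 4-fold changes. Of 1.5-fold changes it recovered 13.4%, 19.4% and 14.9%, and 5, 7 and 4 unchanged probes were called. The simulated noise was independent between probes and arrays, with 1 SD per probe for all groups and no slide effect or outlying array. These rates hold for that setting and not for the real arrays. Each time had the same setting and 1 draw, so differences between the times are random. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.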

Results

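RNA was measured in pooled spinal cord caudal to a complete transection and after a sham operation, to follow the response of the cord of a fish that regenerates it. There were 6 groups of 3 arrays, injury and sham at 4, 12 and 264 h. Between 14757 probes on injury 4 h replicate 1 and 18487 on sham 12 h replicate 1 were well above background, 68.7% and 86.0% of 21495. The 75th percentile of linear intensity was between 901.5 and 1185.5, and spots of the same probe differed by a log2 SD of 0.185 to 0.294. No array had more than 6 saturated spots. The mean correlation of an array with its own group, across probes that are not independent replicates, was between 0.974 for sham 264 h replicate 3 and 0.991 for sham 12 h replicate 1. Each group mean below rests on n = 3 arrays, and changes are injury minus sham. Errors of changes are SE from limma, from 1 spread per probe that all 6 groups share. In every gene that the naming rule took with an adjusted p under 0.05 over all probes, the 3 injured arrays lay beyond all 3 sham arrays, which the rule asks of most of them and which is therefore no separate evidence.

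At 4 h the clearest difference was in immediate early genes, which encode transcription factors and feedback regulators switched on within minutes of a stimulus. Of 32 measured members of that list, 29 had a higher mean after injury, and the list shifted by 0.69 on the log2 scale, adjusted p = 7.53e-19 in camera, with all 3 injured arrays above all sham arrays. No member passed over all probes, and 20 were higher and 0 lower when adjusted over the list alone. Among those 20 were fosb with 2.79, fosab with 1.70 and egr2a with 1.62. Genes of the stress response shifted by 0.29, adjusted p = 6.84e-08, with 36 of 49 higher and 3 of 3 injured arrays above sham. Adjusted over the list alone, 9 stress genes were higher and 0 lower, among them the chaperone hsp70.3 with 2.11 and the growth arrest genes gadd45ga with 1.27 and gadd45ba with 1.21. Both list calls held with an estimated correlation, with adjusted p = 0.0348 and 0.0495.

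Of single probes, 1 of 18504 was higher at 4 h and 0 lower by limma, against 1048 at an unadjusted p under 0.05, where 925 would be expected by chance. It is TC277883, similar to the chaperone cofactor Dnajb9, chosen for naming after its values were seen. It rose 2.21-fold, log2 1.14 with SE 0.15, adjusted p = 0.044. No named gene passed. The 5 with the smallest p and a positive value, each with adjusted p = 0.0543, were slc25a25a (NM_213257), trib3 (NM_212869), rasgef1ba (NM_199829), unc119b (NM_212787) and tgif1 (NM_199567). Their log2 values were 1.48 ± 0.24, 1.14 ± 0.18, 0.84 ± 0.14, 0.83 ± 0.13 and 0.79 ± 0.13. slc25a25a encodes a mitochondrial carrier, and its other probe gave 1.57, while the other probe of tgif1 gave 0.13. trib3 encodes a stress-induced pseudokinase. The 5 with a negative value were gypc with −0.80 (adjusted p = 0.0986), synprb with −0.57 (0.113), tnnt2c with −1.63 (0.139), fzd8a with −0.79 (0.151) and znf503 with −0.44 (0.167). tnnt2c, a troponin, was above background on 0 of 3 injured arrays. It was at least 1.87-fold lower by the bound used here, which depends on the level set for those arrays. Under normexp correction gypc gave 0.07 and tnnt2c 0.10, so their sign depends on the background correction. The median change of all probes was 0.154 there, and both lay below it.

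Other lists moved at 4 h with the preset correlation alone. Skeletal muscle genes, a tissue next to the cord, shifted by 0.43 with 39 of 43 higher, 0 called and 2 of 3 injured arrays above sham, adjusted p = 3.38e-06, but adjusted p = 0.55 with an estimated correlation. Hypoxia and glycolysis genes shifted by 0.25 with 34 of 40 higher and 3 of 3 arrays above sham, adjusted p = 0.000157, and adjusted p = 0.393 with an estimated correlation. Cytokine and innate response genes shifted by 0.18 with 23 of 31 higher and 2 of 3 arrays above sham, adjusted p = 0.00278, and adjusted p = 0.221 with an estimated correlation. Adjusted over the list alone, 3 of them were higher: the transcription factor cebpb with 1.51, the feedback inhibitor socs3a with 1.1 and the cytokine il1b with 0.88. Matrix and wound genes shifted by 0.21 with 36 of 46 higher and 3 of 3 arrays above sham, adjusted p = 0.00663, and adjusted p = 0.573 with an estimated correlation. Their 1 member past the threshold adjusted over the list alone was the integrin itga5 with 1.2. Genes of DNA replication and mitosis shifted by −0.17, with 13 of 59 higher and 1 of 3 injured arrays below all sham arrays, adjusted p = 0.00291, and adjusted p = 0.631 with an estimated correlation. Without sham replicate 1 the muscle shift was 0.18 (adjusted p = 0.0594), without injury replicate 1 the cytokine shift was 0.10 (0.0631), without injury replicate 3 the matrix shift was 0.18 (0.0624), and without sham replicate 3 the cell cycle shift was −0.06 (0.594). Under normexp correction the cell cycle shift was −0.09 (0.0773).

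The remaining 12 lists were not called at 4 h. Shifts and counts of higher members were −0.10 with 14 of 37 for leukocytes and microglia, 0.03 with 9 of 16 for oligodendrocytes, −0.08 with 19 of 42 for ependymal and radial glia, and −0.03 with 16 of 34 for neurons and synapses. They were 0.07 with 22 of 30 for axon growth, −0.03 with 21 of 39 for axon guidance, 0.08 with 22 of 35 for sterols and lipids, and 0.06 with 20 of 30 for skin and pigment. Erythroid genes gave −0.13 with 7 of 22, endothelial genes −0.06 with 10 of 26, and follow-up genes of the field 0.08 with 5 of 5. Ribosomal protein genes had 52 of 71 higher, with a shift just under 0 and an upward test. Axon guidance genes had a median of 0.01 and a downward test. Endothelial genes held 2 higher and 2 lower members adjusted over the list alone, cldn5b with 1.14, tagln2 with 0.97, clec14a with −0.83 and tie1 with −0.73.

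Slide 5 held all 3 injured 4 h arrays and 1 sham array, so the within-slide values rest on that sham array. There, TC277883 gave 1.02 against 1.14 over all arrays, and with slide as a block 3 probes were called, 1 higher and 2 lower. Blocked values were 1.12 for trib3, 1.17 for slc25a25a and 0.90 for unc119b, 0.72 for the immediate early list (adjusted p = 3.85e-12), 0.26 for stress (8.17e-04), 0.25 for hypoxia (0.0056), 0.16 for matrix (0.0367) and −0.38 for the cell cycle (7.27e-10). The muscle shift was 0.19 (0.113) and the cytokine shift 0.10 (0.171), both past the threshold no longer. The count of 1 became 0 without sham replicate 1 or 2 or injury replicate 2 or 3, 4 without sham replicate 3 and 20 without injury replicate 1. Quantile normalization called 16 probes, 87.5% of them higher against 100% of the 1 call, and normexp correction moved the median change of all probes from 0.009 to 0.154.

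At 12 h single named genes passed the threshold, among them heat shock genes and transcription factors. The heat shock gene hsp70 (BC056709) rose 6.34-fold, log2 2.66 ± 0.47, adjusted p = 0.0297. The regeneration-associated transcription factor atf3 (NM_200964) rose 4.79-fold, 2.26 ± 0.23, adjusted p = 0.00232, and the AP-1 factors jun and junbb rose 2.0-fold and 2.64-fold, adjusted p = 0.0192 and 0.0248. ascl1a (NM_131219), a proneural factor that glia express in injured fish retina, rose 2.49-fold, 1.32 ± 0.19, adjusted p = 0.0135. odc1, which makes the first polyamine, also rose 2.49-fold, 1.32 ± 0.23, adjusted p = 0.0289.

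In all, 61 probes were higher and 1 lower at 12 h, 52 of the 62 by at least 2-fold. The lower one, CK360422, was named after its values were seen and changed by −0.56 ± 0.11, adjusted p = 0.0451. The 62 calls held 25 named genes, all higher. Beside those above, the rule named hsp70.3 with 2.60 and the inositol kinase itpk1a with 2.34. It named slc25a25a with 1.85 and a second called probe of 1.59, rhov with 1.55, the phosphatase dusp5 with 1.43, the hexokinase hk2 with 1.33, the complement gene c7b with 1.25 and gadd45ga with 1.13. The adjusted p of these genes was between 0.0121 for slc25a25a and 0.0486 for rhov. A second probe of jun was called with 0.97. The class I MHC gene mhc1uea gave the largest value, 7.64 ± 1.45, adjusted p = 0.0419, which rests on very low signal, under −5 on the log2 scale, on 2 sham 12 h arrays of 18 arrays. Probes of fgb, the fibrinogen beta chain, outside the rule and picked after its values were seen, were called 3 times with 2.21 to 2.68, while another probe of fgb gave −0.87.

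**Figure D1:**
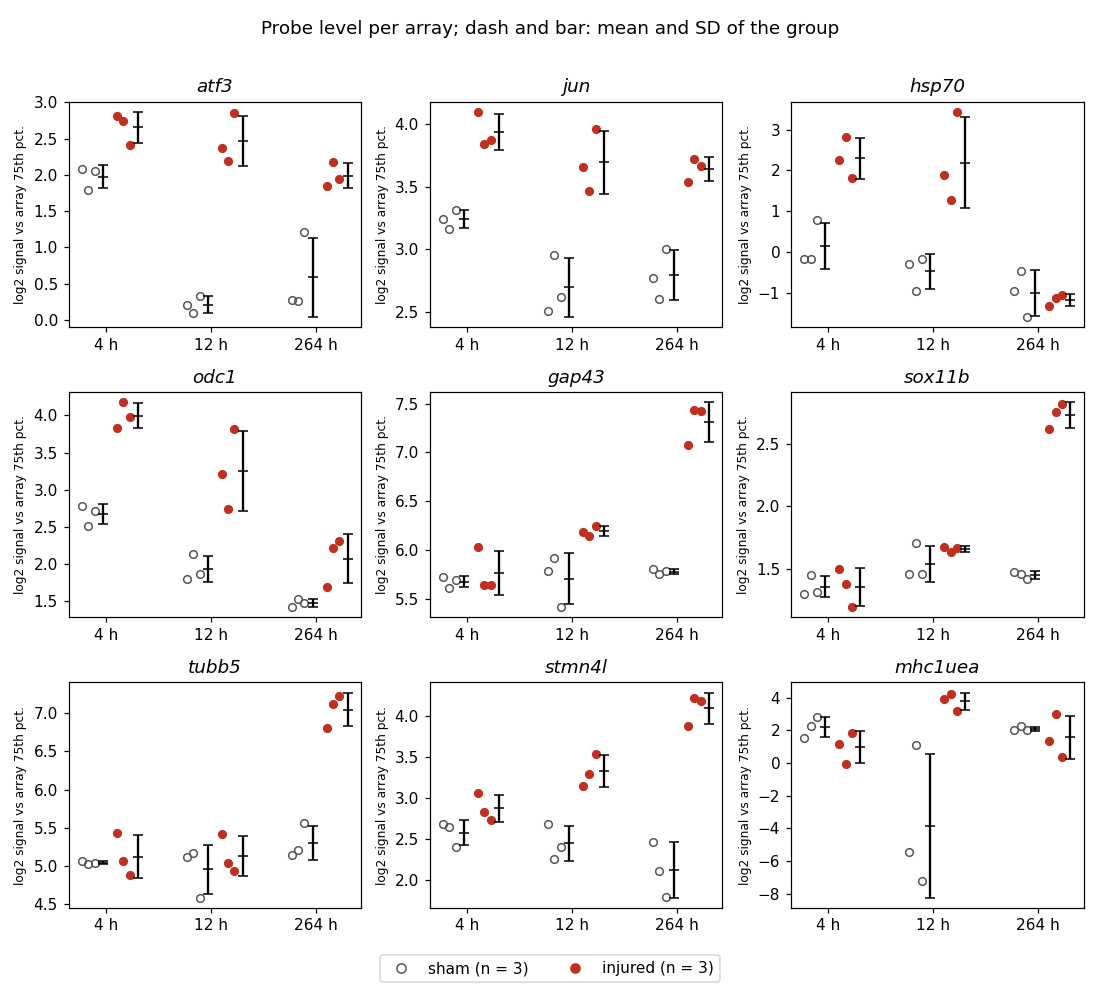
Log2 signal relative to each array's 75th percentile (y) at 4, 12 and 264 h after surgery (x) for 9 genes, with open circles for sham arrays and red filled circles for injured arrays, 3 of each per time, and a dash with a bar for mean and SD. At 264 h the change of gap43 was 1.53 and of sox11b 1.28, and at 12 h that of hsp70 was 2.66.

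Among the lists of 12 h, those of innate and immune genes shifted upward after injury, that of leukocytes with the preset correlation alone. With that correlation, splits that mixed injured and sham arrays shifted up to 8, 10 and 11 lists at 4, 12 and 264 h. These were at least as many as in the real groups, so a preset p alone does not set injury apart from other groupings of the pools. Cytokine and innate response genes shifted by 0.53, with 25 of 31 higher and 3 of 3 injured arrays above sham, adjusted p = 3.34e-07, and held with an estimated correlation, adjusted p = 0.0495. Of these, 1 passed over all probes, c7b, and 6 adjusted over the list alone, among them socs3b with 1.40 and socs3a with 0.97. Leukocyte and microglia markers shifted by 0.56 with 32 of 37 higher, 0 called and 3 of 3 arrays above sham, adjusted p = 1.05e-09, and adjusted p = 0.21 with an estimated correlation. Immediate early genes shifted by 0.53 with 23 of 32 higher and 3 of 3 arrays above sham, adjusted p = 2.79e-09, and adjusted p = 0.0835 with an estimated correlation. Of them, 5 rose over all probes (atf3, jun, junbb, junba and dusp5) and 10 adjusted over the list alone. The stress list shifted by 0.33 with 32 of 49 higher and 3 of 3 arrays above sham, adjusted p = 9.13e-07, and adjusted p = 0.0682 with an estimated correlation. Its members hsp70.3 and gadd45ga rose over all probes and 5 rose adjusted over the list alone, among them gadd45bb with 1.5 and the ER chaperone hspa5 with 0.71. Cell cycle genes shifted by 0.37 with 47 of 59 higher and 3 of 3 arrays above sham, adjusted p = 2.69e-09, and adjusted p = 0.263 with an estimated correlation. Only orc1, a replication origin protein, passed, with 0.45 adjusted over the list alone.

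Smaller list shifts at 12 h were lost with an estimated correlation. Neuron and synapse genes shifted by −0.16 with 4 of 34 higher, 0 called and 3 of 3 injured arrays below sham, adjusted p = 0.00169, and adjusted p = 0.568 with an estimated correlation. Erythroid genes shifted by −0.32 with 3 of 22 higher and 2 of 3 arrays below sham, adjusted p = 0.0295, and adjusted p = 0.55 with an estimated correlation. Ribosomal protein genes, a list whose symbol pattern also takes the kinase rps6kb1b, shifted by 0.09 with 64 of 71 higher and 0 of 3 arrays above all sham, adjusted p = 0.000157, and adjusted p = 0.652 with an estimated correlation. Axon growth genes shifted by 0.17, although their median was −0.01 and 14 of 30 were higher, with 3 of 3 arrays above sham, adjusted p = 0.0152, and adjusted p = 0.51 with an estimated correlation. Of them atf3 rose over all probes and 5 adjusted over the list alone, among them stmn4l with 0.88 and gap43 with 0.48. The 5 measured follow-up genes shifted by 0.34 with 4 of 5 higher and 3 of 3 arrays above sham, adjusted p = 0.0216, and adjusted p = 0.271 with an estimated correlation. That list was drawn from later work of the field and is not independent evidence of its direction. Single arrays ended some of these calls: axon growth gave 0.13 without injury replicate 1 (adjusted p = 0.114) or sham replicate 3 (0.123), erythroid genes −0.21 without injury replicate 1 (0.19) and −0.23 without sham replicate 3 (0.139), ribosomal genes 0.04 without sham replicate 3 (0.0539), and the follow-up genes 0.30 without sham replicate 1 (0.078) and 0.27 without injury replicate 2 (0.0943).

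Not called at 12 h were oligodendrocytes with a shift of −0.08 and 4 of 16 higher, axon guidance with −0.07 and 9 of 39, skeletal muscle with −0.13 and 10 of 43, and endothelium with 0.11 and 14 of 26. Ependymal and radial glia genes gave 0.08 with a median of −0.06 and 17 of 42 higher, ascl1a among them called. Matrix genes gave 0.17 with a median of −0.03 and 21 of 46 higher, and the protease adam8a with 2.67 and the inhibitor timp2b with 1.45 passed adjusted over the list alone. Hypoxia genes gave 0.06 with a median of −0.09 and 16 of 40 higher, and hk2 was called over all probes. Adjusted over the list alone, 4 hypoxia genes were higher, among them igfbp1a with 1.23, and 2 lower, cited2 with −0.50 and pgam1b with −0.37. Sterol genes gave 0.04 with a median of 0.03, a mean of −0.01 and 20 of 35 higher. Skin and pigment genes gave −0.01 with an upward test and 15 of 30 higher, and krt18a.1 with 0.69 passed adjusted over the list alone.

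On slide 3, which held 1 injured and 3 sham arrays of 12 h, the 62 called probes had a median of 1.37 in the called direction against 1.33 over all arrays, a value from arrays that also served to call them. With slide as a block, 1 probe was called. Blocked values were 2.17 for atf3 (adjusted p = 0.194), 2.35 for hsp70 (0.556), 1.57 for slc25a25a (0.384), 1.37 for ascl1a (0.356) and 0.96 for jun (0.499), so these calls ended where 1 injured array carried the contrast. Blocked list shifts were 0.37 for leukocytes (2.43e-04), 0.44 for cytokines (1.68e-05), 0.40 for immediate early genes (1.19e-04), 0.18 for stress (0.00974), 0.28 for the cell cycle (1.68e-05), 0.25 for axon growth (0.00171), 0.09 for ribosomal proteins (0.00256), −0.17 for neurons (0.0164), −0.54 for erythroid genes (7.53e-04) and 0.12 for the follow-up genes (0.388). The count of 62 became 5 without sham replicate 1, 14 without sham replicate 2, 2 without sham replicate 3 or injury replicate 3, and 112 without injury replicate 1, of which 48 were higher and 64 lower. atf3 kept its call in each of these. slc25a25a lost it without sham replicate 1 or 3, jun and ascl1a also without injury replicate 3, and hsp70, hsp70.3, junbb and odc1 further without sham replicate 2. The other named genes, itpk1a, rhov, dusp5, hk2, c7b, gadd45ga and mhc1uea, lost it in at least 4 of the 6 removals, which span every array of 12 h. Under normexp correction itpk1a, rhov, dusp5, c7b and gadd45ga lost their calls.

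At 264 h the genes of axon growth stood out. gap43 (NM_131341), a growth cone protein, rose 2.89-fold, log2 1.53 ± 0.15, adjusted p = 0.000187, and its other probes were called with 1.40 and 1.44. The stathmin stmn4l (NM_001002563) rose 3.95-fold, 1.98 ± 0.18, adjusted p = 0.000145. The tubulin tubb5 (NM_198818) rose 3.34-fold, 1.74 ± 0.19, adjusted p = 0.000643, with other probes at 2.06 and −0.37, which differ in sign. sox11b (NM_131337), a transcription factor of neuronal differentiation, rose 2.42-fold, 1.28 ± 0.11, adjusted p = 8.6e-05. The axon growth list shifted by 0.51 with 24 of 30 higher and 3 of 3 injured arrays above sham, adjusted p = 2.79e-09, and held with an estimated correlation, adjusted p = 0.0495. Of its members 7 rose over all probes, with tmsb, sox11a and atf3 beside those above. Adjusted over the list alone 12 were higher and 1 lower, stmn2a with −0.38.

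Of 138 probes called at 264 h, 98 were higher and 40 lower, 69 by at least 2-fold, and they held 70 named genes, 52 higher and 18 lower. Among genes with a symbol, besides the axon growth genes, the largest rise was that of the cardiac myosin light chain myl7 (NM_131329) with 4.51 ± 0.70. cryba2b (NM_001002584), a lens crystallin, had 0 of 3 sham arrays above background. It rose at least 6.30-fold by the bound used here, which depends on the level set for those arrays. The melanin enzyme gene tyrp1b rose by 2.45 and, on a second probe, by 2.33. myl7 and the Nodal inhibitor lft2, with 1.89, were above background on 1 of 3 sham arrays. Also named were the cytokine receptor gene crlf1a with 2.88 (another probe gave −0.13), the actin-binding genes tmsb with 2.14 and dbnla with 1.72, the laminin lamb4 with 2.0, aqp8a.1 with 1.73 (other probes gave 0.49 and 1.46) and the Notch ligand jag1a with 1.71, whose other probe gave 0.06. Their adjusted p was between 0.00033 for cryba2b and 0.0425 for aqp8a.1. List membership added atf3 with 1.40, jun with 0.85, junba with 0.99, ier5l with 1.16, tgfbi with 1.06, anxa5b with 1.41, icn with 1.44 and col18a1a with 0.97, another probe of which gave −0.23. Among genes with a symbol, the largest falls were those of tspan34b with −1.21 ± 0.21 (adjusted p = 0.0155), tdh with −1.09 and the activin receptor acvr2ba with −1.04 ± 0.14 (0.00267), whose other probe, of far lower signal, gave −0.18. A further fall was that of smarcal1 with −0.97, which was 0.25 under normexp correction, where the median change of all probes was 0.368. Others were ndufa4b with −0.94, rcan3 with −0.83, prkab1a with −0.79, the transcription factor foxb1a with −0.78, the calcium buffer pvalb6 with −0.69, aclya with −0.69, pcmtl with −0.66 and slc25a39 with −0.62.

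The other list calls at 264 h were lost with an estimated correlation. Matrix and wound genes shifted by 0.55 with 38 of 46 higher and 3 of 3 injured arrays above sham, adjusted p = 3.23e-07, and adjusted p = 0.225 with an estimated correlation. anxa5b, tgfbi and col18a1a rose over all probes and 17 rose adjusted over the list alone, among them adam8a with 1.94, the collagen chaperone serpinh1b with 1.56 and the fibronectin fn1a with 0.99. Cell cycle genes shifted by 0.36 with 50 of 59 higher and 3 of 3 arrays above sham, adjusted p = 4.86e-06, and adjusted p = 0.501 with an estimated correlation. None was called over all probes and 5 were adjusted over the list alone, among them orc6 with 1.37, tyms with 1.24 and mcm4 with 0.87. Leukocyte markers shifted by 0.31 with 33 of 37 higher, 0 called and 3 of 3 arrays above sham, adjusted p = 0.0011, and adjusted p = 0.568 with an estimated correlation. On sham replicate 3, 13 of the 37 lay over 0.5 above the other sham arrays. Ribosomal protein genes shifted by 0.11, or by −0.16 under normexp correction, with 67 of 71 higher and 1 of 3 arrays above all sham, adjusted p = 0.00133, and adjusted p = 0.652 with an estimated correlation. Follow-up genes, not independent evidence, shifted by 0.47 with 5 of 5 higher and 3 of 3 arrays above sham, adjusted p = 0.00264, and adjusted p = 0.154 with an estimated correlation. Neuron and synapse genes shifted by −0.24 with 12 of 34 higher and 2 of 3 arrays below sham, adjusted p = 0.00285, and adjusted p = 0.573 with an estimated correlation. pvalb6 fell over all probes, and adjusted over the list alone 6 were lower, such as calb2b with −0.75 and gad1b with −0.47, and 1 higher, inab with 0.83. Skeletal muscle genes shifted by −0.35 with 9 of 43 higher, 0 called and 0 of 3 arrays below all sham, adjusted p = 0.0083, and adjusted p = 0.652 with an estimated correlation. Without sham replicate 2 the muscle shift was −0.14 (adjusted p = 0.273) and the ribosomal shift 0.04 (0.207), without injury replicate 3 the ribosomal shift was 0.02 (0.311), and without sham replicate 1, whose labels conflict, the neuron shift was −0.14 (0.099). Under normexp correction the leukocyte shift was 0.14 (0.144) and that of the follow-up genes 0.20 (0.141), and under quantile normalization the ribosomal shift was 0.06 (0.0556).

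The 11 lists not called at 264 h included immediate early genes, with a shift of 0.05, a median of −0.04 and 14 of 32 higher. Still, jun, junba, junbb, atf3 and ier5l of that list rose over all probes, and adjusted over the list alone 7 were higher and 2 lower, klf2b with −0.71 and nr4a1 with −1.30. Skin and pigment genes gave 0.32 with 21 of 30 higher, adjusted p = 0.0519, tyrp1b and icn among them called. Ependymal and radial glia genes gave 0.18 with 28 of 42 higher, adjusted p = 0.0821, and 4 passed adjusted over the list alone: jag1a, the lipid carrier fabp7b with 1.59, dlb with 1.24 and ascl1a with 0.71. Cytokine genes gave 0.17 with 22 of 31 higher, oligodendrocyte genes 0.12 with 11 of 16 and stress genes 0.05 with 29 of 49. Axon guidance genes gave −0.13 with 16 of 39 higher, erythroid genes −0.17 with 7 of 22, endothelial genes −0.13 with 11 of 26 and hypoxia genes −0.11 with 15 of 40. Sterol genes gave −0.15 with 13 of 35 higher, and aclya, an enzyme of fatty acid synthesis, fell over all probes.

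**Figure D2:**
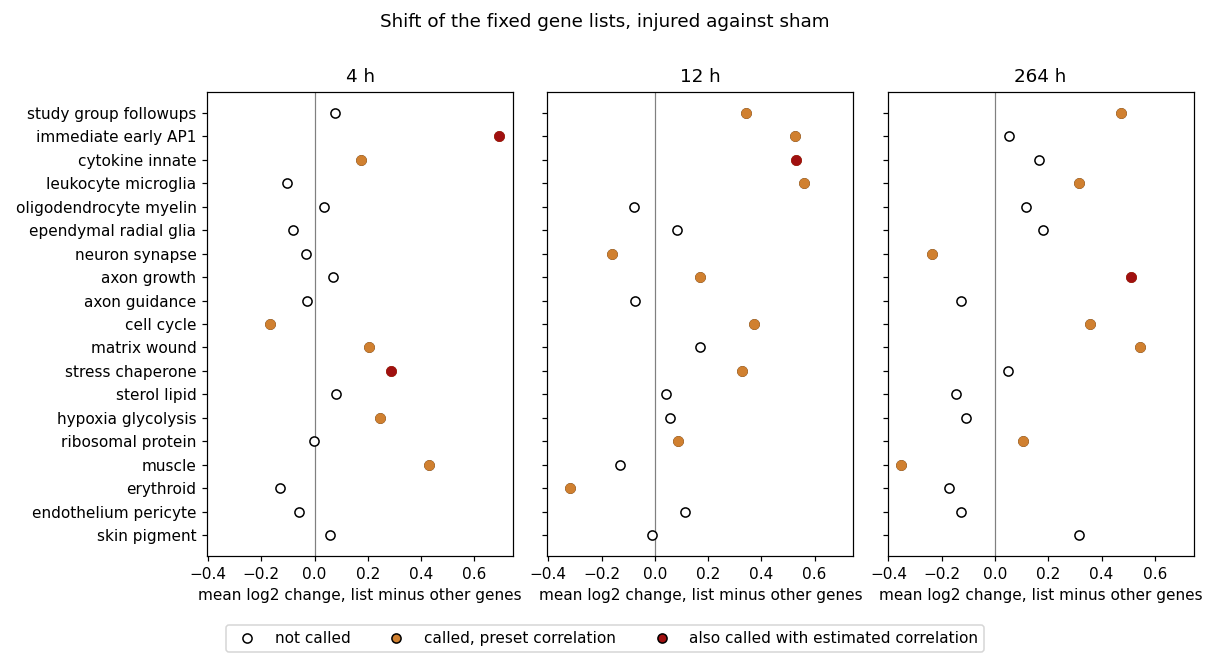
Mean log2 change of each of 19 gene lists minus that of the other genes (x) at 4, 12 and 264 h, 3 panels. Open points were not called, orange points were called with the preset correlation, and dark red points also with an estimated correlation: immediate early (0.69) and stress (0.29) at 4 h, cytokines (0.53) at 12 h and axon growth (0.51) at 264 h.

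Both slides of 264 h held both groups. The 138 called probes had a median of 0.72 in the called direction on slide 1, with 1 array of each, and of 1.17 on slide 2, with 2 of each, the arrays that served to call them. With slide as a block 120 probes were called, 86 higher and 34 lower, while junba, col18a1a, pcmtl and slc25a39 passed no longer. List shifts on slides 1 and 2 were 0.41 and 0.56 for axon growth, 0.39 and 0.62 for matrix, 0.10 and 0.42 for leukocytes, 0.29 and 0.57 for follow-up genes, −0.21 and −0.25 for neurons, and of opposite sign for muscle, 0.07 and −0.56, and for ribosomal proteins, −0.02 and 0.17. The cell cycle list gave 0.17 on slide 1 and 0.46 on slide 2. The count of 138 became 302 without injury replicate 1, 267 without sham replicate 3, 59 without sham replicate 2, 32 without injury replicate 3 and 23 without injury replicate 2, and it was 2 with the array of conflicting labels counted as injured. Lower probes were 40 of the 138, but 2 of the 23, 2 of the 32 and 10 of the 59, against 108 of the 302 and 82 of the 267. The 2 calls with that array counted as injured were lower. With the arrays of 264 h alone, 0 probes were called. In the fit of all arrays, removals of 4 h or 12 h arrays, which share the spread, were not read out for 264 h. gap43, stmn4l, tubb5, sox11b, tmsb, jag1a, dbnla, lft2, cryba2b and acvr2ba kept their calls without any 1 of the 6 arrays of 264 h. Under normexp correction, though, lft2 lost its call with 1.16 (adjusted p = 0.0872) and cryba2b with 1.34 (0.0607), as did jun, junba, anxa5b and smarcal1. myl7, tyrp1b and lamb4 lost theirs without injury replicate 2, and ier5l, rcan3, prkab1a and foxb1a without injury replicate 2 or 3. atf3, tspan34b, tdh, smarcal1, ndufa4b, pcmtl and slc25a39 lost theirs also without sham replicate 2, slc25a39 without sham replicate 3 as well. crlf1a, anxa5b, aqp8a.1, jun, junba, icn, tgfbi, aclya, pvalb6 and col18a1a lost theirs without injury replicate 2 or 3 or sham replicate 1 or 2, and aqp8a.1, junba and col18a1a also without sham replicate 3. Normexp correction moved the median change of all probes from −0.018 to 0.368.

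Genes followed up by later work of the field, and glial markers, are given whether they passed or not. sox11b rose at 264 h, with 0.00 at 4 h, where its sign varied with the scaling, and 0.12 at 12 h. lgmn, a lysosomal protease, gave 0.12, 0.20 and 0.31 at the 3 times, and mvp, the major vault protein, 0.30, 0.68 and 0.22. sdcbp2 gave 0.09, 0.45 and 0.44, and the axonal adhesion molecule cntn2 0.04, −0.01 and 0.32. At 12 h all 3 injured arrays lay above all sham arrays for mvp (adjusted p = 0.296) and sdcbp2 (0.332), as for gap43 with 0.48 (0.2), without passing. gfap, the astroglial filament gene, gave 0.04 at 4 h, with a negative sign under quantile normalization, −0.11 at 12 h and 0.15 at 264 h. atf3 gave 0.68 ± 0.23 at 4 h, adjusted p = 0.538, with 3 of 3 injured arrays above sham. Its mean level relative to the 75th percentile was 1.98 in sham and 2.65 in injured arrays at 4 h, and 0.21 and 2.47 at 12 h, where the change of sham level between times was not tested. The array holds 1 probe for csrp1a, above background on 1 of 18 arrays and so not tested, and 0 probes for mbpa.

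Whether the injury effect itself differed between times was tested by the difference of changes. From 4 to 264 h 11 probes passed, 10 with a higher change at 264 h and 1 with a lower one, against 1966 at an unadjusted p under 0.05. They stand for 7 named genes. The difference was 1.28 ± 0.15 for sox11b, 1.53 and 1.68 for 2 probes of stmn4l, 2.08 and 1.66 for tubb5, 1.41, 1.44 and 1.35 for gap43, 1.11 for sox11a and −1.40 for 1 probe of acvr2ba. The other probe of acvr2ba gave −0.14 at 4 h and −0.18 at 264 h, so this difference, the 1 lower call, rests on 1 of 2 probes, and the third probe of tubb5 was not called. The fitted difference of 3.64 for cryba2b is no measured size, since no injured 4 h and no sham 264 h array was above background for it. Adjusted p was between 0.0135 for sox11b and 0.048 for a probe of tubb5. From 12 to 264 h 1 probe passed of 1436 at an unadjusted p under 0.05, sox11b with 1.16 ± 0.15, adjusted p = 0.0425. From 4 to 12 h limma called 0 probes, against 1411 at an unadjusted p under 0.05, and the smallest adjusted p was 0.454, shared by atf3 with 1.58 ± 0.33, tapbp.1 with 1.39, psme1 with 1.33, sh3gl1a with 1.31, gypc with 1.17 and rasgef1ba with −1.01. Further values the rule names there were −3.91 for oclna (adjusted p = 0.478) and −1.24 for selenot1b, −0.99 for cebpa and −0.50 for ankhb (0.494). Other values the rule names, which did not pass, were −1.48 for tdh, −1.51 for arrdc3a, −1.55 for bag3 and −0.86 for ndel1b from 4 to 264 h. From 12 to 264 h they were 1.64 for crhbp, 1.57 for tubb5, 1.64 for tgfbi, −1.58 for cad, −1.38 for scarb2a, −1.55 for slc25a25a, −1.12 for pcgf6 and −2.84 for hsp70, and cryba2b, at background in both groups of 12 h, had adjusted p = 0.0581.

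With slide as a block, 4 probes passed for the difference from 4 to 264 h, of which acvr2ba with −1.66 (adjusted p = 0.0477) and cryba2b (0.0477, again against groups at background) were among the 11. Blocked values of the others were 1.23 for sox11b (0.0653), 1.38 and 1.51 for stmn4l, 2.02 and 1.66 for tubb5, 1.40, 1.46 and 1.39 for gap43 and 1.07 for sox11a (0.144). For 12 to 264 h sox11b gave 1.14 (0.31) and 0 probes passed. The count of 11 became 0 without injury 264 h replicate 2 or 3 or injury 4 h replicate 2 or 3, 2 without sham 4 h replicate 2 and 3 without sham 4 h replicate 1. It became 19 without sham 264 h replicate 1, 30 without injury 264 h replicate 1, 33 without injury 4 h replicate 1 and 38 without sham 264 h replicate 3. Where the count moved less, 4 of the 11 probes still lost their calls without sham 264 h replicate 2, those of sox11a (adjusted p = 0.0922) and 1 probe each of gap43 (0.0557), tubb5 (0.126) and stmn4l (0.0578). Without sham 4 h replicate 3, sox11a (0.0931), 2 probes of gap43 (0.0641 and 0.0582) and 1 of tubb5 (0.114) lost theirs, and without sham 264 h replicate 1, 1 of tubb5 (0.076). The 1 probe from 12 to 264 h became 0 without injury 264 h replicate 2 or 3, sham 264 h replicate 1 or 2, sham 12 h replicate 1 or 3 or injury 12 h replicate 2. It became 2 without injury 12 h replicate 3, 9 without sham 264 h replicate 3, 10 without injury 264 h replicate 1 and 12 without injury 12 h replicate 1. sox11b itself lost this call in 9 of 12 removals, those that gave 0 and those of injury 12 h replicate 3 (adjusted p = 0.0626) and sham 12 h replicate 2 (0.0701), where the 1 call was of another probe, with a lower change at 264 h. From 4 to 12 h, 1 probe was called without sham 12 h replicate 2.

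Calls at 12 and 264 h shared 11 higher probes, against 0.323 expected if the calls were independent. These stood for actb1, atf3, jun, junba, junbb and stmn4l besides unnamed sequences. Calls at 4 and 12 h shared 1, TC277883, against 0.003 expected. All times share 1 estimate of spread per probe, so their calls are not independent and the expected counts can be too low. Of the 61 probes higher at 12 h, 56 had a positive change at 4 h with a median of 0.52, and 50 had one at 264 h with a median of 0.54. Across 6509 genes, which are not independent replicates, changes correlated between 12 and 264 h with r = 0.26 and rho = 0.31, between 4 and 12 h with r = 0.05, and between 4 and 264 h with r = 0.01. Slide 4 held most sham arrays of 4 h and most injured arrays of 12 h. An effect of that slide enters the changes of 4 and 12 h with opposite signs and can lower their correlation. The 11 shared probes became 1 without injury 12 h replicate 3, 2 without sham 12 h replicate 3 or injury 264 h replicate 3, 3 without injury 264 h replicate 2, and 4 without sham 12 h replicate 1 or sham 264 h replicate 2. They became 7 without sham 12 h replicate 2 or sham 264 h replicate 1, 17 without injury 264 h replicate 1 and 21 without sham 264 h replicate 3.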

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

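Of the tests reported here, those on the slide behind the 12 h calls, on leukocytes and array quality behind sham 264 h replicate 3, and on heart, lens and pigment cells were chosen after the values they measure were seen. That on sequence variants was prompted by the pattern it bears on, with criteria set before its values were seen, and the splits were fixed before.

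The differences below drew attention because the injury effect at 1 time differed from that at another in a test of the difference itself, with the adjusted p given in the report. Between 4 and 264 h the difference was 1.28 for sox11b, 1.11 for sox11a, and 1.53 and 1.68 for 2 probes of stmn4l. It was 2.08 and 1.66 for 2 probes of tubb5, 1.41, 1.44 and 1.35 for 3 probes of gap43, and −1.40 for 1 of 2 probes of acvr2ba. For cryba2b the fitted value was 3.64, which is no measured size, since no injured 4 h and no sham 264 h array was above background for it. Between 12 and 264 h it was 1.16 for sox11b. Of the 12 differences, 2 stayed past the threshold with slide as a fixed block. For the difference from 4 to 264 h, 7 of 100 drawn splits of the arrays, the real one among them, called at least as many probes as the real 11. The highest other count was 59. Of 79 splits that regrouped both times 0 reached 11, so those that did kept the real groups of at least 1 time. For 12 to 264 h it was 12 of 100, with 1 real call and 490 as the highest other. Of 80 splits that regrouped both times 1 reached the real count. The shares of 100 thus mix chance with the injury effect and cannot decide whether chance made these calls. For 4 to 12 h the real count was 0 and the highest other 107; with 0 real calls all 100 of 100 splits reach it by construction, so this count says nothing about chance. Splits that call several times the real count point to a structure of the samples: the highest ones were the real groups with the labels of 1 time exchanged, which adds the injury effects of both times instead of subtracting them. Among splits that regrouped both times the highest counts were 1, 1 and 4.

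For the comparisons within a time there are 10 splits of 6 arrays, too few for a share under 0.05. At 4 h the real split called 1 probe and the highest other 1, with 2 of 10 at least as high. At 12 h the real split called 62 and the highest other 1, with 1 of 10 as high, and at 264 h 138 against 3, again 1 of 10. For lists the real count at 4 h was 7 and the highest other 8, with 3 of 10 splits at least as high. At 12 h both were 10, in 2 of 10 splits. At 264 h the form of camera used for the splits, which takes the fitted statistics of the probes, gave 9 against 11, with 3 of 10. The split with 11 lists grouped injury 264 h replicate 1 with sham replicates 2 and 3.

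The first pattern weighed is that injured and sham arrays of 12 h lay mostly on different slides, so the calls may stem from the slides. If so, the probes higher at 12 h should have no tendency to be higher at 264 h, where each slide held as many injured as sham arrays. Of them 82% were higher there, against 47.7% of all probes and at most 68.9% in 10000 random sets of probes matched on level. Counted by gene name or identifier, 40 of 48 were higher. The random sets held separate probes, whereas called probes share genes and can move together, so these sets may be too narrow a comparison. The share went against what slides alone would give, but slides as the whole source of the 12 h calls are not excluded. How much of each change stems from them stays open, because only 1 injured array of 12 h lay beside sham arrays. A response to injury, which the design names, stays a hypothesis.

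The second pattern is sham 264 h replicate 3, which had 352 probes over 4-fold from the median of the other arrays, where each other array had between 30 and 166. A poor hybridization stays open. Its spot SD of 0.276 and its 17062 probes above background lay within the ranges of the other arrays. Such array-wide values cannot show a fault limited to part of the probes. This array also had the lowest mean correlation with its own group, 0.974, and the lowest array weight, 0.389. More leukocytes in that pool may contribute and stay open: the median deviation of the leukocyte list was 0.09, with 21 of 37 members higher and an upper quartile of 0.76, so its members went both ways. Genes of granulocytes, picked after their values were seen, lay far above the other arrays on 1 probe and its companion, lyz with 2.96 and 2.75, mmp9 with 2.24 and 2.17 and npsn with 2.36 and 1.05. Sequence variants under single probes stay open as well: in 56 genes with a far probe the other probes of the gene deviated the same way by a median of 1.17. The 95% interval of 0.72 to 1.62 spans the bound of 1 set beforehand. Of these genes 18 followed by under 0.5 and 30 by over 1.

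The third pattern is the rise at 264 h of genes best known from lens, heart and pigment cells, cryba2b, myl7 and tyrp1b, for which carry-over of tissue is a candidate explanation. The median was −0.15 for 6 tested heart genes and 0.21 for 16 lens genes, but a low median, the criterion set at first, excludes neither tissue. Of the 5 heart genes beside myl7, only 2, with a median of −0.15, had a sham level at least 1 below the injured level of myl7, −3.0, and in the other 3 a small share would be hidden. Of the 15 lens genes beside cryba2b, 11 had a sham level at least 1 below its injured level, −4.5, with a median of 0.23, but 8 of these were not above background on all injured arrays. Carry-over of heart and of lens thus stays open. So does that of pigment cells: the median of 9 pigment genes was 0.14, but it was 1.1 for the 6 above background on all sham arrays, with tyrp1b at 2.45, rpe65a at 2.04 (adjusted p = 0.0564) and pnp4b at 1.77 (0.0709), a second probe of which was called with 1.97 (0.0332). The skin and pigment list shifted by 0.32 (adjusted p = 0.0519), with 3 of 3 injured arrays above sham. Expression of these genes in injured cord itself stays a hypothesis that was found and tested on the same data.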

How the results depend on the processing

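All alternatives were fixed before the data were examined except the fit without slide 1, which was chosen after seeing the data. No paired analysis was possible because the labels carry no numbers that tie an injured pool to a sham pool. Alternatives for the array with conflicting labels and for slide 1 were not read out for the 4 h and 12 h counts and their difference. These share only the estimate of spread with the arrays concerned.

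The 49 called values of named genes had 899 values under alternatives: 630 kept direction and call, 268 kept direction without passing and 1 reversed. Of 516 values for the 25 called lists, 452 kept the call, 63 lost it and 1 reversed. List values and counts under alternatives, except with an estimated correlation or fry, came from a form of camera that takes the fitted statistics of the probes. A moved list call or count can thus stem from that form as well as from the named change. Of 299 values for the 12 called differences, 168 kept it and 131 lost it. Leaving out the array with conflicting labels is the same fit as leaving out sham 264 h replicate 1 and is counted once in these totals. With slide as a fixed block 30 of 49 genes, 2 of 12 differences and 22 of 25 lists kept their calls. Under normexp correction 38 of 49 genes did, and with no filter on dim probes 39 did. Without slide 1, 30 of the 34 genes called at 264 h did. With the arrays of the compared times alone 0 of 49 genes kept their calls. Fewer arrays leave fewer degrees of freedom, and the spread then comes from these arrays alone. The fit of all arrays takes 1 spread per probe for 6 groups, though groups can differ. For crlf1a the SD in sham and injured arrays was 0.12 and 0.19 at 12 h but 0.89 and 1.23 at 264 h. An SE can thus be too small or too large at a given time, and which of these ended the calls was not tested. Under array weights all 49 genes and 12 differences kept their calls, with weights from 0.389 for sham 264 h replicate 3 to 3.69 for injury 264 h replicate 2.

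The count at 4 h (1) was 16 with quantile normalization, 16 with the filter on 9 arrays, 20 with a trended and robust prior, 195 with array weights, 3 with slide as a fixed block, and 0 with the other percentile, normexp correction, no filter, the arrays of the time alone or slide as a random block. The count at 12 h (62) was 27 with normexp correction, 2 with the arrays of the time alone, 1 with a fixed block, which leaves 1 injured array on the slide it shares with sham, and 1604 with array weights, of which 695 were higher and 909 lower. The count at 264 h (138) was 279 with normexp correction, 0 with the arrays of the time alone, 354 with the trended prior, 676 with array weights and 2 with the disputed array counted as injured; without slide 1 it was 194.

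For differences, array weights called 187 from 4 to 12 h (0), 304 from 4 to 264 h (11) and 38 from 12 to 264 h (1), and the trended prior called 28 from 4 to 264 h and 12 from 12 to 264 h. From 4 to 264 h normexp correction called 0, the arrays of these times alone 1, the fixed block 4, the disputed array left out 19, counted as injured 0, and the fit without slide 1 29. From 12 to 264 h normexp correction, no filter, the arrays of these times alone, the fixed block, either use of the disputed array and the fit without slide 1 each called 0. The 11 probes shared by 12 and 264 h became 4 with normexp correction, 0 with the arrays of each time alone, 0 with the fixed block, 20 with the trended prior, 179 with array weights, 7 with the disputed array left out and 0 with it counted as injured. Of the 25 list calls, 4 remained with an estimated correlation and 8 with fry, which tests a list without comparing it with other genes.

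With 1 array of the times concerned left out at a time, the counts lay between 0 and 20 at 4 h, 2 and 112 at 12 h, and 23 and 302 at 264 h. For differences they lay between 0 and 1 from 4 to 12 h, 0 and 38 from 4 to 264 h, and 0 and 12 from 12 to 264 h. They lay between 1 and 21 for shared probes, and 24 and 28 for lists.

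Reversed values were, under normexp correction, 0.25 for smarcal1 and −0.16 for the ribosomal list at 264 h, and 0.066 for gypc, 0.10 for tnnt2c and −0.021 for sox11b at 4 h. Under that correction the median change of all probes was 0.154 at 4 h and 0.368 at 264 h, above the values of these genes. At 4 h sox11b was also −0.023 with quantile normalization, −0.015 with the other percentile and −0.010 with array weights, gfap −0.047 with quantile normalization, and cntn2 −0.17 with a fixed block. At 12 h gfap was 0.071 with a fixed block and cntn2 0.26 with array weights, and at 264 h gfap was −0.052 with the disputed array counted as injured. With 1 array left out at a time, values that crossed 0 lay at 4 h between −0.069 and 0.082 for sox11b, −0.054 and 0.25 for lgmn, −0.037 and 0.14 for cntn2, −0.039 and 0.16 for gap43 and −0.027 and 0.12 for gfap. They lay at 12 h between −0.26 and 0.13 for cntn2 and −0.26 and 0.064 for gfap, and at 264 h between −0.004 and 0.54 for mvp. For all these changes the cause was not tested. Signal over background limits the dim probes: 2991 were left untested, and 14124 of 21495 were above background on all arrays.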

Other observations

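Some class I MHC probes had very low signal on part of the arrays and high signal on the rest, a pattern picked after the values were seen. mhc1uea was under −5 on the log2 scale on 2 of 18 arrays, sham 12 h replicates 1 and 3, and at −0.05 or above on the remaining arrays. mhc1uxa2 was under −5 on 9 of 18 arrays, 4 sham and 5 injured, and at 0.76 or above on the rest. The change of mhc1uea at 12 h rests on those 2 arrays.

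Arrays of the same group correlated with a mean r of 0.988 on the same slide (10 pairs) and 0.984 on different slides (8 pairs), across probes that are not independent replicates. Arrays of the other treatment at the same time gave 0.985 on the same slide (11 pairs) and 0.984 on different slides (16 pairs). The first 4 principal components held 20.9%, 15.2%, 10.8% and 8% of the variance. Along the first, the arrays of slide 4, of sham 4 h and injury 12 h, lay between −5.9 and 2.1. All arrays of slides 3 and 5 lay higher, between 16.5 and 39.6, whatever their treatment. Injury 12 h replicate 1 was at 39.6 and sham 4 h replicate 3 at 20.5, beside the arrays of their slides. At 4 and 12 h this component thus followed slide more than treatment.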
